A study of Homo sapiens with 4 samples.

How the data were processed

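Total RNA of 4 cultures of K562/G01 cells was depleted of ribosomal RNA from 3 µg of input and made into libraries with a kit that keeps strand, per the labels' protocols. FastQC, HISAT2 and HTSeq 0.6.1 and the build GRCh38 are named in the submitters' processing notes; the annotation release, the strand setting of the counting and the sequencing run are not given in the sources used here. The authors deposited 1 table with 28482 genes and, per the file headers, a read count and an FPKM value per gene for each of the 4 libraries. The deposited counts are whole numbers and were used as deposited. The deposited FPKM columns were treated as a score rather than as FPKM, because 6 genes (TACC3, PGR, GZMB, MPP2, CLCN3 and SCN7A) have negative values; every value equals the deposited count scaled by the total of the deposited counts and by a whole number per gene (tolerance 0.001) in the place of a length, which is negative for these 6. These columns were used only for alternatives, without the 6 genes. Gene identifiers were matched to GENCODE release 29 on GRCh38, where 28329 matched and 26313 had the same version, and this annotation gave gene types and positions. Without a stated strand setting, genes that overlap another gene or its antisense partner are uncertain, as are near-identical copies such as HBA1 and HBA2 or the HIST2H2AA genes. The table had 0 rows of small RNA classes, so the list of small structured RNAs was not measured.

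Totals of the counts lay between 30634832 and 34095585 per library. The 10 most abundant genes took 8.60% of the counts in the scramble library, 8.91% in the knockdown library, 8.65% in the scramble library with imatinib and 9.87% in the knockdown library with imatinib, and mitochondrially encoded genes took 6.76%, 7.32%, 6.94% and 8.28% in the same order. TMM factors were 0.9996, 0.9937, 1.01 and 0.9965. Genes with a CPM of 1 or more in at least 2 libraries were kept, 13296 in all. A log2 ratio is that of TMM-normalised CPM with a prior count of 2, and its 95% interval is the exact binomial interval of the counts of the 2 libraries, which covers counting error only, since reads are not independent molecules. A count of 0 allows up to 3 counts.

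The labels give 1 library per group and do not say whether the cultures were infected or treated separately. The 5 pairs of groups, knockdown over scramble without and under imatinib, imatinib over none in scramble and in knockdown cells, and both over neither, were therefore compared as sizes, with counts of genes at 2-fold or more and no p-value. The effect of knockdown over both imatinib states and that of imatinib over both knockdown states were tested with the quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) in an additive design with both factors over all 4 libraries, with Benjamini-Hochberg adjustment over 13296 genes. This leaves 1 residual degree of freedom, the interaction, so a gene whose knockdown change depends on imatinib has a larger error; information shared across genes added 33.7 prior degrees of freedom, and the common biological coefficient of variation was 0.0783. The interaction itself was computed as a difference of ratios and not tested.

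Gene lists were fixed before the data were examined, 35 in all, of which 34 had at least 3 members that passed the filter. Each list's median log2 ratio was placed among 10000 random lists of the same size drawn from the same 20 expression bins, as a description of these libraries, and a list is called shifted where it lay in the lowest 2.5% or the highest 2.5% on the same side in both pairs. The rule for named genes was also fixed before. It takes TCF7; the 12 protein-coding genes highest and the 12 lowest for knockdown and for imatinib, ranked by the smaller of the 2 absolute log2 ratios with the same sign in both pairs and a mean CPM of 5 or more; the 6 highest and 6 lowest for the interaction and for knockdown with imatinib over scramble; of each list up to 6 members at 2-fold or more in both pairs or else up to 4 with the largest change at a mean CPM of 1 or more; and ABCC2, ABCB1, ABCG2, ABCC1, MYC, CTNNB1, LEF1, TCF7L1, TCF7L2, AXIN2, CCND1, BCR, ABL1, BCL2L11, BCL2, GATA1, HBG1, HBG2 and CD34. XIST and Y-linked genes were left out. Some genes that the rule names are not reported here.

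Alternatives were other scalings (DESeq2 size factors, total counts), no filter and a filter at 5 CPM, a prior count of 0.5, log2 of deposited FPKM plus 0.1, counts thinned to the smallest library, a fold limit of 1.5, DESeq2 1.42.0, limma 3.58.1, the fit without the other factor, and each library left out. After the data were seen, a smooth trend of each log2 ratio over GC content and length of the longest GENCODE transcript was removed (mgcv 1.9.3, available for 13255 genes), the same trend per library was entered as offsets in edgeR, and rolling medians over 21 neighbouring genes were computed along the chromosomes for 10098 genes at a mean CPM of 5 or more. In the window search, odd-ranked genes of the knockdown pair without imatinib defined a stretch, and even-ranked genes of the pair under imatinib tested it.

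The additive edgeR fit, the list step, the stretch search and trend removal from ratios were tested on simulated data with known answers; the fit with offsets, DESeq2, limma and the fits without the other factor were not. In counts drawn from these libraries' means for 13296 genes, edgeR called 74%, 82%, 100% and 100% of genes changed 1.5-, 2-, 4- and 8-fold by knockdown, 68%, 94%, 94% and 100% of those changed by imatinib, and 0.0916% of unchanged genes in each. The simulated counts had no GC trend, interaction or difference between cultures. These shares therefore do not give the rate of false calls in the deposited libraries. The list step found a list moved by -0.3 and 0 of 33 others, and the stretch search found a planted run of 60 genes and 0 others over 10098 genes. That run is longer than the 17 genes of the stretch reported below. Trend removal on 13255 genes took a planted GC trend from a Spearman correlation of 0.523 to -0.014 and kept planted changes at a median of 2.02 log2 units where 2 had been planted. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the lists, windows and plots.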

Results

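RNA was measured by sequencing in K562/G01 cells, a derivative of the K562 line that resists imatinib. K562 is an established line from chronic myeloid leukemia and carries the BCR-ABL1 fusion kinase that imatinib inhibits. The cells carried a lentiviral short hairpin RNA against TCF7, a transcription factor of the Wnt pathway, or a scramble hairpin. Each of these was left untreated or given imatinib at 1 µM for 48 hours, which makes 4 groups with 1 library each. The deposited counts summed to 33146606 in the scramble library, 30634832 in the knockdown library, 34095585 in the scramble library with imatinib and 31744915 in the knockdown library with imatinib. No group has a replicate, so a ratio between 2 libraries has no replicate check, and its 95% interval covers counting error only. A change was tested only for knockdown over both imatinib states and for imatinib over both knockdown states, where 2 libraries stand against 2. The error is the disagreement between the pairs, mostly pooled over genes (33.7 prior against 1 residual degree of freedom). A called gene can therefore have pairs that differ in size. The p-values of this test measure the spread between these libraries. The labels do not say whether the cultures were infected separately. A lasting difference between knockdown and scramble cultures would therefore also be called as knockdown, and the test cannot tell it from an effect of TCF7. The verbs rose and fell are used below only for genes that passed it at an adjusted p under 0.05. Of 28482 genes in the table, 13296 passed the expression filter.

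The targeted gene was compared first. TCF7 (ENSG00000081059.19; GRCh38 chromosome 5, 134114711 to 134151865) had 339 counts in the scramble library and 78 in the knockdown library, or 10.25 CPM (counting interval 9.19 to 11.41) against 2.57 CPM (2.03 to 3.20). Under imatinib the counts were 367 and 117, or 10.68 CPM (9.62 to 11.83) against 3.71 CPM (3.07 to 4.44). The knockdown libraries thus held 25.04% (19.3% to 32.1%) and 34.7% (27.9% to 42.8%) of the TCF7 level of their scramble libraries. TCF7 fell with knockdown over both imatinib states (log2 fold change -1.75, SE 0.206, edgeR adjusted p = 1.53e-07), lower in 2 of 2 pairs. The ratio of imatinib over no imatinib was 0.06 in scramble cells and 0.52 in knockdown cells on the log2 scale, and TCF7 was not called for imatinib (edgeR adjusted p = 0.398).

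**Figure D1:**
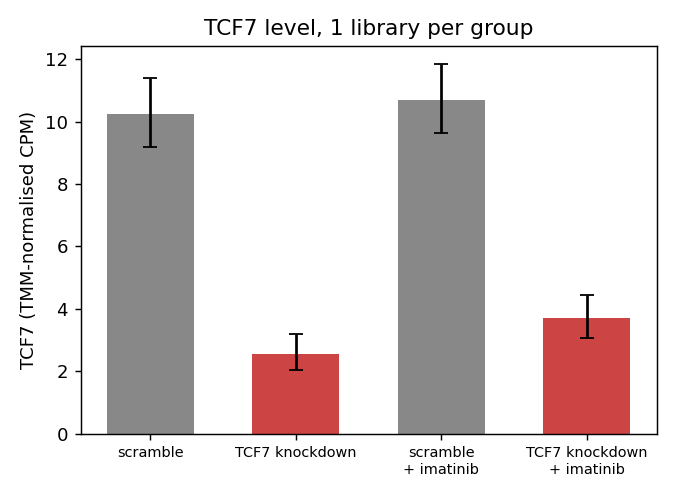
TCF7 level in each of the 4 libraries, as CPM scaled by TMM factors on an axis that starts at 0; error bars are exact Poisson 95% intervals and cover counting error only. The knockdown libraries sit at 2.57 and 3.71 CPM, below 10.25 and 10.68 CPM in the scramble libraries.

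The question of the knockdown comparison is which transcripts differ when TCF7 is reduced in these resistant cells, with and without the drug. Among protein-coding genes at a mean of 5 CPM or more, ranked by the smaller of their 2 ratios, those highest with knockdown were SPARC, a secreted matrix glycoprotein, SLAMF6, a receptor of lymphoid cells, PLXNA2, a semaphorin receptor, and TRANK1. SPARC had log2 ratios of 1.90 (counting interval 1.70 to 2.13) without imatinib and 1.85 (1.64 to 2.08) under imatinib, SLAMF6 1.64 and 2.13, PLXNA2 1.56 and 1.76, and TRANK1 1.70 and 1.46. Those lowest were MT2A, a metallothionein that binds zinc and copper, B3GAT1, a glucuronyltransferase, TCF7 itself and ALDH1L2, a mitochondrial enzyme of folate metabolism. MT2A had log2 ratios of -2.18 (-2.56 to -1.86) without and -3.50 (-4.10 to -3.08) under imatinib, B3GAT1 -1.62 and -2.20, and ALDH1L2 -1.53 and -1.47.

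Other genes of the ranking were also at 2-fold or more in both pairs. Higher were LSR, a lipoprotein receptor (1.39 and 1.59), CYTIP (1.33 and 1.87), HPGD, which inactivates prostaglandins (1.68 and 1.28), AIM1 (1.23 and 1.49), IL1RL1, an interleukin receptor of mast cells and basophils (1.30 and 1.23), EPX, the eosinophil peroxidase (1.80 and 1.11), and IER3IP1 (1.08 and 1.14). Lower were MAP3K21, a protein kinase (-1.45 and -1.49), ANKH, a pyrophosphate transporter (-1.48 and -1.33), SPIRE1, an actin nucleator (-1.44 and -1.23), SLC1A4, a transporter of neutral amino acids (-1.12 and -1.17), ITGB4, an integrin subunit (-1.11 and -1.18), NDRG1, a gene induced by hypoxia (-1.35 and -1.10), IGF1R, a growth factor receptor (-1.10 and -1.14), and SCN2A, a sodium channel subunit (-1.10 and -1.40). All 12 genes ranked highest rose and all 12 ranked lowest fell, with a largest edgeR adjusted p of 0.000215 among the 24, and DESeq2 called the same 24 genes. The ranking picked large ratios of the same sign from the same libraries, so these calls are no separate check of the genes.

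**Figure D2:**
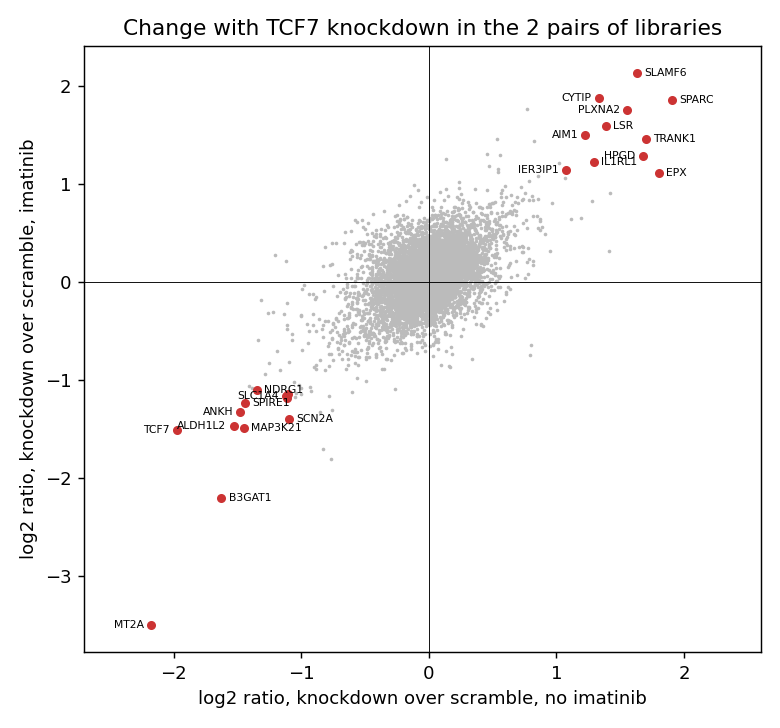
Each point is a gene at a mean of 5 CPM or more; the axes give its log2 ratio of knockdown over scramble without imatinib (horizontal) and under imatinib (vertical). Red points are the genes named from the ranking, with ITGB4 and IGF1R unlabelled beside SLC1A4; MT2A lies lowest at -2.18 and -3.50 and SPARC farthest right at 1.90 and 1.85.

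Genes of glycolysis and the hypoxia response were lower with knockdown as a group. The median of the 28 measured members was -0.21 without imatinib and -0.36 under imatinib, below all 10000 random lists matched on expression in each pair. Of these members 15 fell, 0 rose and 13 were not called (21 fell and 1 rose adjusted over the list alone). Among those that fell were ALDOC, an aldolase (-1.04 and -1.13), VEGFA, the endothelial growth factor (-0.76 and -1.31), P4HA1, a collagen prolyl hydroxylase (-0.60 and -1.12), and LDHA, lactate dehydrogenase (-0.34 and -0.62).

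Genes of the integrated stress response, which raises amino acid synthesis and transport when translation initiation is restrained, were lower too. The median of 26 measured members was -0.39 without and -0.18 under imatinib, again below all random lists. Of these members 12 fell, 0 rose and 14 were not called (14 fell adjusted over the list alone). SLC7A5, a transporter of large neutral amino acids, had ratios of -1.16 and -0.89, DDIT4, an inhibitor of mTOR signalling, -0.77 and -1.81, and ATF3, a transcription factor of the response present at a low level, -1.57 and -1.28, and all of these fell. ABC transporters, the family that includes drug efflux pumps, had medians of -0.19 and -0.20 over 17 measured members (percentile 0.12 in each pair), of which 4 fell and 0 rose (5 fell adjusted over the list alone). Those that fell included ABCA3 (-1.19 and -0.70), ABCC4 (-0.39 and -0.52) and ABCA2 (-0.69 and -0.29).

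Other groups were higher with knockdown. Chaperones and other genes of the unfolded protein response had medians of 0.17 and 0.12 over 21 members, above all random lists and at percentile 99.76, of which 7 rose and 0 fell (9 rose adjusted over the list alone). HSPA5 had ratios of 0.36 and 0.36, CALR 0.44 and 0.53 and SDF2L1 0.29 and 0.50, and all of these transcripts, which encode endoplasmic reticulum proteins, rose. G1/S genes had medians of 0.09 and 0.16 over 28 members, at percentile 99.94 and above all random lists, of which 3 rose, among them MCM6 (0.51 and 0.46) and TK1 (0.28 and 0.30), and 0 fell (4 rose adjusted over the list alone). Interferon-stimulated genes had medians of 0.31 and 0.41 over 10 measured members of 33 listed, of which 1, BST2 (0.49 and 0.53), rose and 0 fell (2 rose adjusted over the list alone), and the shift was lost among genes at 5 CPM or more. The 13 mRNAs encoded by mitochondrial DNA had medians of 0.12 and 0.33, and 7 of them rose and 0 fell (12 rose adjusted over the list alone), among them MT-ND2 (0.16 and 0.51) and MT-CYB (0.21 and 0.48), so that the larger ratios are those of the knockdown library with imatinib. With the GC and length trend described below removed, the mitochondrial median without imatinib lay at percentile 92.78 and the list was no longer shifted in both pairs.

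**Figure D3:**
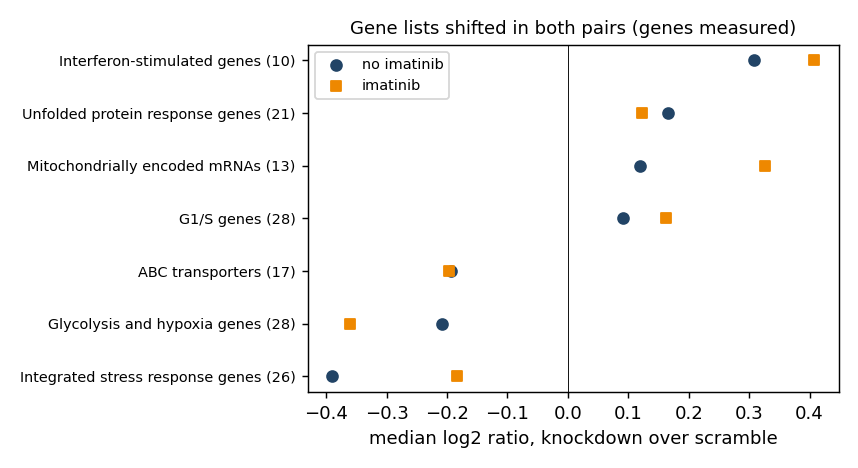
Median log2 ratio of knockdown over scramble for the 7 gene lists that lay outside the central 95% of matched random lists on the same side in both pairs, with the number of genes measured in brackets. Circles are the pair without imatinib and squares the pair under imatinib; the integrated stress response (-0.39 and -0.18) and glycolysis and hypoxia (-0.21 and -0.36) lie lowest.

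The Wnt target genes were not shifted with knockdown as a list, where 949 of 13296 genes were called in all. Of the drug pump genes named in advance only ABCC2 and ABCC1 could be tested, and 0 were called. The 14 measured Wnt target genes had medians of -0.01 and 0.09 (percentiles 39.3 and 76.9), with 1 risen, TCF7L2 (0.34 and 0.59), 1 fallen, VEGFA, which the hypoxia list also holds, and 12 not called (the same counts adjusted over the list alone). Not called were LEF1 (0.12 and -0.43), AXIN2 (0.26 and 0.18), CCND1 (-0.06 and 0.15), MYC (0.03 and 0.05) and CTNNB1, which encodes beta-catenin (0.03 and -0.08). ABCC2 had ratios of -0.72 (-1.27 to -0.22) and -0.25 (-0.74 to 0.21) and was not called (edgeR adjusted p = 0.448), and ABCC1 had ratios of -0.28 and -0.03. ABCB1 had 11, 4, 13 and 0 counts in the scramble, knockdown, scramble with imatinib and knockdown with imatinib libraries, where a count of 0 allows up to 0.0945 CPM. ABCG2 had 1, 0, 1 and 1, TCF7L1 5, 0, 6 and 16, and CD34 1, 1, 0 and 1. These 4 genes were below the expression filter. BCL2L11, which encodes the pro-apoptotic protein BIM, rose with ratios of 0.28 and 0.32 (edgeR adjusted p = 0.0314).

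In all, 356 of 13296 genes were at 2-fold or more without imatinib, 123 higher and 233 lower with knockdown, and 376 under imatinib, 175 higher and 201 lower. The pairs share no library, but a lasting difference between knockdown and scramble cultures would enter both. Across genes, which are not independent replicates, the log2 ratios of the pairs had a Pearson correlation of 0.44. In both pairs 52 genes were 2-fold higher and 75 2-fold lower, against 1.62 and 3.52 for independent lists. That baseline treats every gene as equally likely to reach 2-fold, and genes with low counts reach it more often, so it is too low. At a mean of 5 CPM or more, 18 and 25 genes were 2-fold higher in the 2 pairs, 13 of them in both. There 39 and 30 were 2-fold lower, 20 of them in both. The additive edgeR fit called 949 genes for knockdown, 505 that rose and 444 that fell, where 2577 genes had an unadjusted p under 0.05 against 665 by chance. With GC and length offsets, chosen after seeing the data, it called 1654, 858 higher and 796 lower. DESeq2 called 272 and limma on deposited FPKM values 195. Without a term for imatinib the fit called 0 genes (818 at an unadjusted p under 0.05); in that form it called 34 without the scramble library, 747 without the knockdown library, 49 without the scramble library with imatinib and 226 without the knockdown library with imatinib. Genes with low counts made up most of the 2-fold genes, since 68 and 64 remained among those at 5 CPM or more in at least 2 libraries.

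A run of neighbouring genes on chromosome 8 was lower in both knockdown libraries, and it was singled out after the values were seen. Between 51817575 and 57984126 (GRCh38), from PCMTD1 to LINC01602, all 17 genes at a mean of 5 CPM or more were lower with knockdown in both pairs, with medians of -0.57 (SD 0.169 over the 17 genes) and -0.64 (SD 0.170). Of these 17 genes 16 fell. They include LYN, a SRC-family kinase (-0.57 and -0.68), RPS20, a ribosomal protein (-0.56 and -0.71), ATP6V1H, a subunit of the lysosomal proton pump (-0.50 and -0.49), RB1CC1, a component of the autophagy initiation complex (-0.46 and -0.63), and PLAG1, a zinc finger transcription factor (-0.81 and -0.90). The ratios of imatinib over no imatinib of the same genes had medians of -0.13 in scramble and -0.21 in knockdown cells. LYN, RPS20 and ATP6V1H are also members of the lists of BCR-ABL signalling components, ribosomal proteins, and autophagy and lysosome genes. The 7 lists shifted with knockdown hold 0 genes of the stretch.

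**Figure D4:**
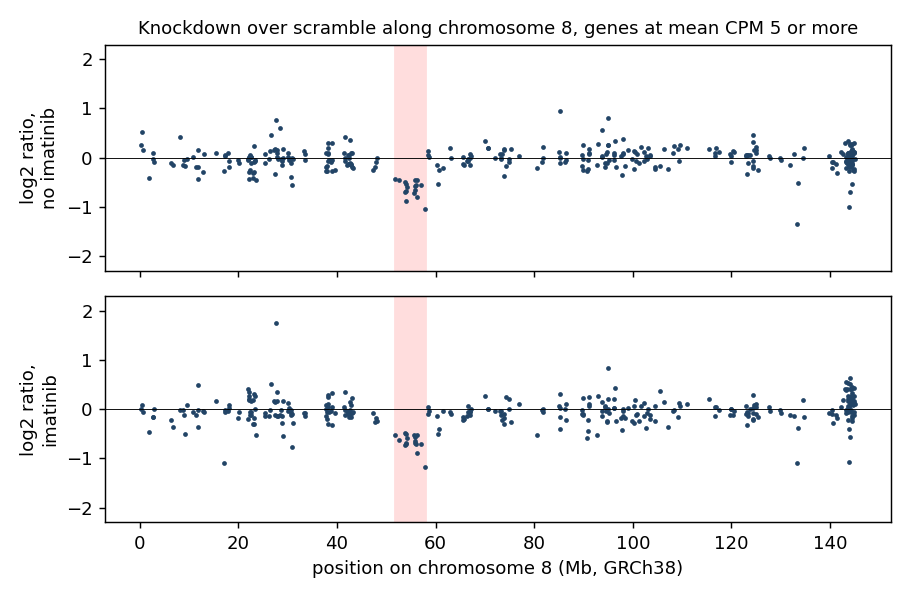
Log2 ratio of knockdown over scramble for each gene at a mean of 5 CPM or more along chromosome 8 (position in Mb, GRCh38), without imatinib (top) and under imatinib (bottom). The shaded stretch holds 17 genes with medians of -0.57 and -0.64, while most points farther along the chromosome scatter around 0. To its right UBXN2B had 0.14 and -0.09, but beyond that RAB2A (-0.53 and -0.50) and CHD7 (-0.26 and -0.39) were lower.

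The imatinib comparison asks what the drug changes in cells selected to resist it. The level of a gene under imatinib went with its GC content in these libraries. Over 10098 genes at a mean of 5 CPM or more, the Spearman correlation across genes between GC content and the log2 ratio of imatinib over no imatinib was 0.68 in scramble cells and 0.75 in knockdown cells. The 1839 genes that rose with imatinib had a median GC content of 60.2% and 940 genes that fell and could be matched 39.7%, against 47.3% for all 13255 tested genes that could be matched. The same correlation was -0.11 for knockdown without imatinib and 0.37 for knockdown under imatinib. The counts of the imatinib comparison, most of its gene groups and some of its genes are therefore also given with a smooth trend over GC content and transcript length removed from each ratio, or entered per library as offsets in the test, corrections chosen after seeing the data.

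**Figure D5:**
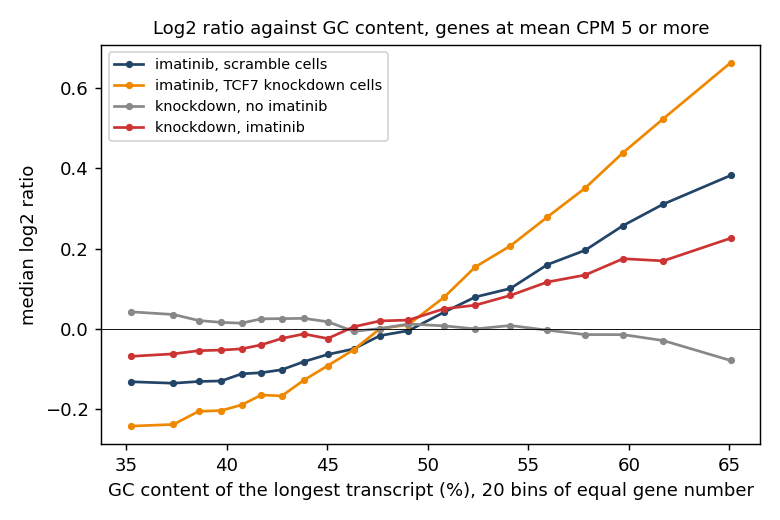
Median log2 ratio in 20 bins of equal gene number by GC content of the longest annotated transcript (%), for genes at a mean of 5 CPM or more; each line is 1 pair of libraries. The imatinib ratio in knockdown cells runs from -0.24 in the bin lowest in GC to 0.66 in the highest, and that in scramble cells from -0.13 to 0.38.

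KIT, a receptor tyrosine kinase that imatinib also inhibits, ranked lowest under imatinib by the smaller of its 2 ratios, with log2 ratios of -0.91 in scramble and -1.39 in knockdown cells. It fell over both knockdown states (edgeR adjusted p = 0.000149, and 1.42e-05 with GC and length offsets). HIST2H2AA4, a histone gene with a near-identical copy whose reads cannot be told from its own, had ratios of -0.73 and -1.45. NDUFC2, a subunit of respiratory complex I (-0.51 and -0.68), and DNAJB9, an endoplasmic reticulum chaperone (-0.46 and -0.75), also fell. The genes ranked highest were EMC6 (1.15 and 1.19), HPS6 (1.08 and 1.01), TIGD5 (0.96 and 1.32), PPDPF (0.94 and 1.68), MEX3D (0.94 and 1.11), ARMC5 (0.98 and 0.93), HBA2, an alpha-globin gene nearly identical in coding sequence to HBA1 and therefore uncertain (0.99 and 0.92), TRMT61A (0.95 and 0.88), ZNF707 (0.85 and 0.86), C9orf16 (0.85 and 1.22), C19orf60 (0.85 and 1.03) and C8orf82 (0.85 and 1.23). Their GC content lay between 55.5% and 68.2%. All 12 rose, and 7 of them were still called with the offsets. With the trend removed only EMC6 (0.92 and 0.84), C19orf60 (0.67 and 0.75) and TIGD5 (0.56 and 0.66) stayed among the 12 ranked highest. HPS6 then had 0.68 and 0.36, HBA2 0.57 and 0.21, and TRMT61A 0.55 and 0.205. The others ranked lowest were DEPDC4, SYT1, GKAP1, CREBRF, BTG3, ALDH1L2, ZNF670 and MORC4, with ratios between -0.46 and -0.77. Of the 12 ranked lowest 10 fell, all but ALDH1L2 and MORC4, and 7 were called as lower with the offsets. DESeq2 called 11 of the 12 ranked highest and 4 of the 12 ranked lowest. This ranking too used the same libraries as the tests, so the calls are no separate check.

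Genes of the BCR-ABL pathway showed small ratios. The 27 measured signalling components had medians of 0.02 and 0.04 under imatinib (percentiles 91.8 and 93.8), with 8 risen, 3 fallen and 16 not called (9 risen and 3 fallen adjusted over the list alone). ABL1 had ratios of 0.27 and 0.40 and BCR 0.22 and 0.43, and both rose. With the trend removed their ratios were -0.01 and -0.07 for ABL1 and -0.08 and -0.06 for BCR, and the list medians -0.03 and -0.05. With the offsets 0 of the components were called higher and 1 lower. STAT5 target genes, read out downstream of BCR-ABL1, had medians of 0.20 and 0.25 over 16 members with a median GC content of 55.6%, and 8 rose and 1 fell (the same counts adjusted over the list alone), among them PIM3 (0.68 and 0.71), SOCS1 (0.66 and 1.07) and CCND3 (0.34 and 0.62). With the trend removed the medians were 0.11 and 0.02, at percentiles 99.99 and 92.83, and the list was no longer shifted in both pairs. PIM3 then had 0.22 and -0.06, SOCS1 0.15 and 0.22 and CCND3 0.14 and 0.31, and with the offsets 2 STAT5 target genes were called higher and 0 lower. ERK output genes had medians of 0.19 and 0.24 (percentiles 99.35 and 96.16), with 6 risen and 0 fallen (7 risen adjusted over the list alone), among them IER2 (0.68 and 0.91) and JUNB (0.59 and 0.79). With the trend removed the ERK medians were 0.09 and 0.00 (percentiles 99.71 and 67.18), IER2 had 0.35 and 0.37 and JUNB 0.18 and 0.13, and with the offsets 1 member was called higher.

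Other lists stood apart under imatinib before the trend was removed. Wnt pathway components (median GC content 54.6%) had medians of 0.11 and 0.35 over 28 genes, with 13 risen and 1 fallen (the same counts adjusted over the list alone), among them DVL1 (0.45 and 0.89). DVL1 had -0.02 and 0.10 with the trend removed, and with the offsets 3 components were called higher and 0 lower. TGF-beta target genes (57.9%) had 0.20 and 0.33 over 14 genes, with 5 risen and 1 fallen (8 and 1 adjusted over the list alone). Replication-dependent histone genes (49.7%) had 0.12 and 0.06 over 21 genes, with 9 risen and 0 fallen (10 and 1 adjusted over the list alone). HIST2H2AA4, which was lower, is not a member of this list. MYC target genes (51.0%) had 0.06 and 0.04 over 30 genes, with 9 risen and 1 fallen (10 and 1 adjusted over the list alone), and MYC itself rose (0.27 and 0.29, or 0.12 and 0.07 with the trend removed, and not called with the offsets, edgeR adjusted p = 0.353). Ribosomal protein genes (47.9%) had medians just below 0 (0.00 and -0.05 over 78 genes) and yet lay above most random lists of genes as highly expressed, with 12 risen and 16 fallen (12 and 18 adjusted over the list alone), a shift that was lost among genes at 5 CPM or more. G2/M genes (42.6%) were lower, with medians of -0.11 and -0.23 over 29 genes and 2 risen and 11 fallen (2 and 13 adjusted over the list alone), among them CENPE (-0.23 and -0.52, or -0.12 and -0.30 with the trend removed). With the offsets 0 G2/M genes were called higher and 4 lower. With the trend removed none of these 6 lists was shifted in both pairs; the medians were 0.02 and 0.06 for Wnt pathway components, -0.01 and 0.10 for TGF-beta target genes, 0.10 and 0.00 for histone genes, 0.01 and -0.06 for MYC target genes, -0.02 and -0.08 for ribosomal protein genes and -0.05 and -0.13 for G2/M genes. The histone median in scramble cells still lay above all random lists, and 6 histone genes were called higher and 2 lower with the offsets. The 13 mitochondrially encoded mRNAs had medians of 0.05 and 0.30, with 6 risen and 1 fallen (the same counts adjusted over the list alone), and stayed shifted with the trend removed (0.09 and 0.35, at percentile 99.99 and above all random lists). With the offsets 8 of them were called higher and 1 lower. Here too the larger median is that of the knockdown library with imatinib.

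In scramble cells 174 genes were at 2-fold or more with imatinib, 111 higher and 63 lower, and in knockdown cells 493, 351 higher and 142 lower. With the trend removed the counts were 140 (70 higher and 70 lower) and 267 (118 higher and 149 lower). Among genes at 5 CPM or more in at least 2 libraries they were 5 and 138, and 1 and 29 with the trend also removed. The log2 ratios of the pairs had a Pearson correlation of 0.45 across genes. It was 0.19 with the trend removed. Among genes at 5 CPM or more in at least 2 libraries it was 0.709 with the trend left in. Both ratios followed GC content (Spearman correlations of 0.68 and 0.75), so the shared trend can raise that value. In both pairs 34 genes were 2-fold higher and 8 2-fold lower, against 2.93 and 0.67 for independent lists. That baseline is too low for the reason given for knockdown. At a mean of 5 CPM or more, 2 genes were 2-fold higher in both (3 in scramble and 123 in knockdown cells) and 0 lower in both (1 and 11). The additive edgeR fit called 2780 genes, 1839 that rose and 941 that fell, where 4570 genes had an unadjusted p under 0.05 against 665 by chance. With GC and length offsets it called 725, 255 higher and 470 lower, of which 413 were among the 2780 in the same direction. DESeq2 called 1003 and limma on deposited FPKM values 1094. Without a term for knockdown the fit called 0 genes (2651 at an unadjusted p under 0.05). In that form, with 1 library left out, the number of calls again depended on which library it was. These groups also differ in knockdown, so the calls are not counted here.

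Knockdown with imatinib was also set against the untreated scramble library, the combination against neither treatment. Among protein-coding genes at a mean of 5 CPM or more MT2A ranked lowest, with a log2 ratio of -3.41, followed by ALDH1L2 (-2.03), B3GAT1 (-1.91), MAP3K21 (-1.82), SCN2A (-1.78) and FAM178B (-1.72). LSR ranked highest with 2.14, followed by PLXNA2 (1.85), SPARC (1.83), VSIR, an immune checkpoint receptor (1.77), CLU, a secreted chaperone (1.74), and SLAMF6 (1.73). With the GC and length trend removed LSR (1.54) lay below SPARC (1.82), SLAMF6 (1.80), AIM1 (1.75), CYTIP (1.70) and PLXNA2 (1.685). VSIR then had 1.38, and FAM178B (-2.24) lay below B3GAT1 (-2.20) and ALDH1L2 (-1.89). Glycolysis and hypoxia genes had a median of -0.30 (below all random lists) and integrated stress response genes -0.27 (percentile 0.03). Interferon-stimulated genes had 0.81 (99.99) over 10 measured members of 33 listed. Their shift with knockdown was lost among genes at 5 CPM or more. In total 631 genes were at 2-fold or more, 376 higher and 255 lower, and 463 with the trend removed, 174 higher and 289 lower. This ratio comes from 2 libraries and was not tested.

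The difference between the knockdown change under imatinib and that without imatinib has no residual degree of freedom and was not tested. Among protein-coding genes at a mean of 5 CPM or more it was most positive for OSGIN1, a gene induced by oxidative stress (1.48), ZBTB47 (1.33), NINJ1 (1.21), DNAJC17 (1.17), CEBPB, a myeloid transcription factor (1.17), and DHRSX (1.17). It was most negative for ZNF140 (-1.54), MT2A (-1.32), EMILIN2 (-1.10), DDIT4 (-1.04), HBA1 (-1.04) and ATP1B2 (-0.94). For OSGIN1 the knockdown ratio was -1.21 without and 0.28 under imatinib, and for DDIT4 -0.77 and -1.81. Nuclear genes of the respiratory chain had a median of 0.08 without and -0.04 under imatinib over 41 members, 0 of which were called for knockdown, and the median difference of -0.14 lay below all random lists. Mitochondrially encoded mRNAs had a median difference of 0.23, above all random lists, and mitochondrially encoded genes took 8.28% of the counts in the knockdown library with imatinib against 6.76% to 7.32% in the others. NF-kB and inflammatory genes had -0.18 and 0.41 over 10 members, again with 0 called, and a median difference of 0.60 at percentile 99.99. The 6 of them at 5 CPM or more in at least 2 libraries had medians of -0.18 and 0.14 (percentiles 5.16 and 74.84). In all 493 genes differed by 1 log2 unit or more, 282 with the higher ratio under imatinib and 211 with the lower, and 34 among genes at 5 CPM or more in at least 2 libraries. The count was 452 with the trend removed, 247 higher and 205 lower. The GC content of a gene went with the ratio of knockdown with imatinib over scramble too (Spearman correlation 0.652), and the list medians given for that ratio and for the difference are without the correction.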

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

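The results in this part stand out because the ratio of a named gene points one way in 1 pair of libraries and the opposite way in the other. With 1 library per group the difference was not tested for any of them, and each value is the second log2 ratio minus the first. For knockdown over scramble, without and then under imatinib, CEBPB had -0.82 and 0.35 (difference 1.17), DHRSX -0.65 and 0.51 (1.17), DNAJC17 -0.56 and 0.61 (1.17), NINJ1 -0.58 and 0.63 (1.21), OSGIN1 -1.21 and 0.28 (1.48) and ZNF140 0.80 and -0.74 (-1.54). For imatinib over no imatinib, in scramble and then in knockdown cells, CA2, a carbonic anhydrase, had 0.55 and -1.16 (-1.72), FN1, which encodes fibronectin, -0.28 and 0.84 (1.12), HBA1, whose reads overlap those of HBA2, 0.53 and -0.51 (-1.04), TAP1, a peptide transporter of antigen presentation, 0.79 and -1.16 (-1.95), DHRSX -0.48 and 0.69 (1.17) and ZNF140 0.81 and -0.73 (-1.54). DHRSX and ZNF140 appear in both comparisons with 1 and the same difference, since the 2 differences are equal by construction. The mean level was 1.53 CPM for CA2 and 1.02 CPM for TAP1, so few reads carry those ratios. With the GC and length trend removed, a correction chosen after seeing the data, the differences lay between -2.10 (TAP1) and 1.26 (OSGIN1), and each kept its sign. The genes were flagged for differences of 1 log2 unit or more, so a kept sign is a weak check.

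The most prominent pattern is the imatinib response itself, which held more genes at 2-fold or more in the knockdown libraries (493 against 174, a ratio of 2.83) and mostly upward in the additive fit; the test of depth was chosen only after this result was seen, as were the GC settings. Thinning all libraries to the smallest total left a ratio of 2.74 (2.36 to 3.22), above the limit of 1.5 set for depth as the cause. The totals lay close together (30634832 to 34095585 counts), so thinning removed few reads and is a weak test. Removing the GC and length trend left 1.91 (1.58 to 2.35), also above the limit. The count itself fell from 493 to 267 in knockdown cells and from 174 to 140 in scramble cells. The ratio therefore cannot exclude that the trend gives part of the excess. The intervals of both ratios come from resampling genes and do not cover variation between cultures. They describe these libraries and do not bear on a difference between knockdown and scramble cells. The ratio also depends on the expression limit. At 5 CPM or more in at least 2 libraries 138 genes stood against 5, so genes with low counts made up nearly all of the 174 in scramble cells. With the trend also removed 29 genes stood against 1 at that limit. For the count of calls the trend did meet its prediction, since 725 genes were called with GC and length offsets against 2780 without; that 255 of them were higher was seen afterwards and was not predicted. A hypothesis is that most of the calls may come from a GC trend between the imatinib and other libraries; whether it arose in library preparation or in the cells cannot be told from 1 library per group, and a biological explanation was not tested.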

How the results depend on the processing

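All counts shift with the limits that define them, and the cause of a moved count was not tested except where the setting itself tests fewer genes or libraries. The 2-fold counts below are given in the order knockdown without imatinib, knockdown under imatinib, imatinib in scramble cells, imatinib in knockdown cells, both together, and the difference of the knockdown changes. With no filter on low counts they were 4078, 3942, 3157, 4534, 4313 and 6183, and at 5 CPM or more 68, 64, 5, 138, 185 and 34. At a fold limit of 1.5 the first 5 were 1220, 1324, 900, 2052 and 2367. On deposited FPKM values knockdown without imatinib gave 225 and imatinib in scramble cells 110. In settings chosen after seeing the data, removal of the GC and length trend gave 267 for imatinib in knockdown cells (118 higher and 149 lower, or 44.2% higher against 71.2%). At 5 CPM or more with the trend removed the counts were 66, 65, 1, 29, 92 and 25. Of the tests, knockdown and then imatinib, DESeq2 called 272 and 1003, limma on FPKM values 195 and 1094, edgeR with GC and length offsets 1654 and 725 (for imatinib 35.2% higher against 66.2%), and edgeR without the other factor 0 and 0. Leaving out 1 library in turn, also without the other factor and with the lone library assumed to vary like the others, gave 34 to 747 and 0 to 579. The correlation between pairs was 0.337 as Spearman for knockdown. For imatinib it was 0.709 at 5 CPM or more with the trend left in, and 0.186 over all genes with the trend removed. Of the 15 list shifts, 9 lists were shifted with the trend removed, 7 of them the same, and the mean of the 2 imatinib medians of MYC target genes turned from 0.05 to -0.024. Scaling by size factors or totals kept the counts it was run for within 1.5 times, and so did a prior count of 0.5 and thinning for the 2-fold counts. Of 1325 values of named genes, 8 lay outside their counting interval with size factors, 13 on FPKM values, 597 with the trend removed and 0 with the other prior; the sign turned for 5, 12, 146 and 0 of them, in 0 cases for a value at 2-fold or more. Of the named genes called by edgeR, 0 of 92 for knockdown and 13 of 136 for imatinib turned sign with the offsets. Depth limits the ratios of genes near 1 CPM. No paired analysis by replicate number was possible because each group has 1 library; the additive fit compares each factor within the states of the other.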

Other observations

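Lineage genes were among those called for knockdown, though none of their lists was shifted in both pairs. Of 7 measured megakaryocyte genes, GP6, a collagen receptor of platelets (-1.10 and -0.82), and TUBB1, the platelet tubulin (-0.79 and -0.65), fell and RAB27B (0.70 and 0.81) rose (1 rose and 4 fell adjusted over the list alone). Of 43 erythroid genes 3 rose, CA1 (0.95 and 0.32), ALAD (0.58 and 0.72) and ALAS2 (0.74 and 0.30), and 3 fell, SLC4A1, the anion exchanger (-0.81 and -1.21), CPOX (-0.27 and -0.60) and SLC25A37 (-0.46 and -0.53). Adjusted over the erythroid list alone 3 rose and 6 fell, and with GC and length offsets 3 were called higher and 10 lower. Among 11 granulocyte and monocyte genes SPI1 (0.21 and 0.57) and ITGAM (0.90 and 1.26) rose and 0 fell. Of 11 stem and progenitor genes 2 rose, among them GATA2 (0.10 and 0.48), and 3 fell, IL1RAP, a receptor subunit studied as a marker of leukemic stem cells (-1.17 and -2.63), LMO2 (-0.33 and -0.79) and MECOM (-0.34 and -0.47) (3 rose and 4 fell adjusted over the list alone). AXL, a receptor tyrosine kinase, rose (0.97 and 0.81). Among 9 measured markers of adherent packaging or stromal cells COL1A1 (2.76 and 2.02, at a mean of 0.688 CPM) and FN1 (0.14 and 1.26) rose, and the list medians were 0.00 and 0.22 (percentiles 50.65 and 98.02). ALAS2, CPOX, SLC25A37, LMO2, MECOM and COL1A1 fall outside the naming rule and were chosen after their values were seen.

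Under imatinib GATA1 rose (0.40 in scramble and 0.56 in knockdown cells), but with the GC and length trend removed its ratios were 0.10 and 0.09 and with the offsets it was not called (edgeR adjusted p = 0.459). The fetal globin genes HBG2 (-0.25 and -0.39) and HBG1 (-0.12 and -0.36), which share sequence, fell, with ratios of -0.24 and -0.36 and of -0.11 and -0.33 with the trend removed. Of 11 pro-apoptotic BCL2 family genes 4 rose, among them BBC3, which encodes PUMA (1.27 and 1.29, or 0.74 and 0.41 with the trend removed), and 2 fell, and with GC and length offsets 0 were called higher and 2 lower. Cholesterol synthesis genes had medians of -0.06 and -0.06 over 24 genes, with 3 risen and 8 fallen, with CYP51A1 (1.06 and 1.09, at a mean of 1.69 CPM) among those that rose and SC5D (-0.31 and -0.99) and FDFT1 (-0.25 and -0.42) among those that fell. With the trend removed, a setting chosen after seeing the data, their medians were -0.11 and -0.23 (percentile 0.33 and below all random lists), and those of glycolysis and hypoxia genes -0.08 and -0.23 (percentile 0.83 and below all random lists).

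Genes of glycolysis and hypoxia and of the integrated stress response were lower with knockdown in both pairs, and technical explanations were tested with settings added after the data were seen. With the GC and length trend removed the highest of the 4 percentiles, from 2 lists and 2 pairs, was 0, so the trend does not account for the pattern. The chromosome 8 stretch holds 0 members of these lists. A hypothesis is that reduced TCF7 lowers both programs, but culture density, medium or oxygen could act on the same genes. The labels give a range of density for the line but no value per library, and neither that explanation nor an effect of TCF7 was tested, so both stay open.

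The run of lower genes on chromosome 8 was found by a search chosen after the data were seen, and the test for fewer copies was written only after the result. Of the even-ranked genes of the stretch, which did not define it, 8 of 8 (100%) were lower under imatinib, as fewer copies of the stretch in the knockdown cultures would give. The median of those genes was -0.615 with the GC and length trend removed, and 0% of 1000 shuffles of the gene order gave a window as low, which leaves little room for a trend or a chance run. A hypothesis is that the knockdown cultures may carry fewer copies of this 6.17 Mb stretch than the scramble cultures, or the scramble cultures more, so that the lower LYN and RPS20 need not follow from TCF7. DNA copy number was not analysed here.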
